A study of Mus musculus with 9 samples.

How the data were processed

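Poly(A) RNA was measured by sequencing in 9 mouse hearts, 3 from transgenic mice given vehicle, 2 from transgenic mice given JIB-04 and 4 from wild type mice given vehicle, with groups, replicate numbers and days of collection (125 or 158) taken from the labels. The series text describes dosing until day 158, while 4 hearts are labelled day 125, and the labels of the hearts were used. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a kit that does not keep strand. Per the submitters' processing notes, STAR 2.7.1a, Picard, GATK 4.1.2 and Cufflinks 2.2.1 were used with the GRCm38 genome. The notes do not state which tool did which step, and the annotation release was not given in the sources used here. Per the file headers, the deposited values are log2 values of FPKM, 1 file per heart. The constant added before the logarithm is not stated. The lowest value was exactly 0 in every file and no value was below 0, as a constant of 1 gives, and 1 was used. No scaling between hearts is recorded.

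Each file lists the same 43154 genes with symbol and locus (43088 symbols, 58 of them on more than 1 line, which were kept apart). Loci count from 0, since the start plus 1 equalled the annotated start in 82.9% of 39331 genes matched by symbol and chromosome to GENCODE release M21. Positions are printed counting from 1. That release also gave gene types and exon overlaps. Total read counts are not in the files. The relative depth of each heart was estimated from the size of the steps between low FPKM values, in 2773 to 3239 genes per heart. Between 10.0% and 30.9% of the summed FPKM lay on the mitochondrial chromosome. In 7 hearts mt-Atp6, mt-Atp8 and mt-Co3 were listed at 0, while high in transgenic vehicle heart 3 and JIB-04 heart 2. These 2 hearts also had the largest mitochondrial shares (29.8% and 30.9%), which include these genes. In order, they were at 28963.5, 50185.1 and 35807.1 of 682945 summed FPKM in transgenic vehicle heart 3. In JIB-04 heart 2 they were at 29964.2, 47642.8 and 38913.0 of 661960. The larger shares are therefore not a separate observation. Whether the 2 hearts share a technical difference was not tested. In wild type heart 2 mt-Co1 and mt-Co2 were listed at 0, while high in the others.

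Genes with at least 1 FPKM in at least 2 hearts (13487) were fitted on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with a mean per group and a term for the day of collection, over all 9 hearts. This left 5 residual degrees of freedom, to which the shared prior added 3.07. P-values are two-sided, adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The comparisons were transgenic vehicle against wild type vehicle, JIB-04 against transgenic vehicle, JIB-04 against wild type vehicle, and day 158 against day 125. Differences of an effect between the days came from a fit of the 6 combinations of group and day. Ppp3ca and Rcan1 were compared between all transgenic and all wild type hearts by exact two-sided permutation tests. Gene lists were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with limma's fry, adjusted over 35 lists within a comparison. They comprise 10 main lists, 12 lists of other responses and 13 lists of cell type markers. Acta1, Cox4i1, Rpl13, Hbb-b1, Hbb-b2 and Riox1 were not analysed here. Riox2 was taken as Mina and Adgre1 as Emr1. Groups that share hearts were compared with 100 simulations of unchanged groups.

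The comparisons, tests, filter, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Ppp3ca and Rcan1, the 5 called genes with the largest rise and fall whose replicates do not overlap between groups, up to 3 called members of each main list by size of change (for a list with none, the 2 with the highest level, as values), and up to 2 members of the other lists by p-value. Genes named in one comparison were followed in the others. The alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter of 5 FPKM, scaling to equal totals, median of ratios, quantile normalization, scaling without mitochondrial and the 20 highest genes, no term for day, the replicate number as a block, robust or untrended variance, only the compared groups, day 158 hearts only, and leaving out each heart in turn. Protein-coding genes only was added after the data were seen. The fit was tested on simulated data with 200 changed genes of 13487 in each of 5 runs, in which 4.24% of the genes called for transgenic vehicle against wild type and 5.63% of those called for JIB-04 against vehicle were false. Simulated lists of 30 genes shifted by 0.5 were called in 5 of 5 runs by camera and fry in both comparisons. Unshifted lists were called in 0 of 5 runs, except 1 of 5 by fry for transgenic vehicle against wild type. The simulated genes varied independently of each other, so these runs do not test lists whose genes vary together. Of the named genes, 2 are not reported here, 1 of them with a wild type heart set apart, but both stay in the counts. Summaries and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.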

Results

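Messenger RNA was sequenced from 9 hearts of C57BL/6 mice in 3 groups. Transgenic mice carried calcineurin A, a calcium-activated phosphatase that drives heart growth, under the α-myosin heavy chain (MHC) promoter, which is active in cardiomyocytes. They received vehicle (3 hearts) or JIB-04 (2 hearts), a small molecule inhibitor of the Jumonji histone demethylases, at 50 mg/kg, 3 times a week from 4 weeks of age. Wild type mice received vehicle (4 hearts). No wild type hearts with JIB-04 were analysed here. Hearts were collected at day 125 (transgenic vehicle heart 1, JIB-04 heart 1, wild type hearts 1 and 2) or at day 158 (the other hearts). Levels are given as FPKM, fragments per kilobase of transcript scaled to the mapped fragments, and fold changes as differences of log2(FPKM + 1), a scale that understates changes of genes at low levels. Of 43154 listed genes, 13487 reached 1 FPKM in at least 2 hearts and were tested. The number of reads per heart was not given in the sources used here. Steps between low values put the depth of the hearts at 1.0 to 1.5 times that of wild type heart 1. Correlations of heart pairs across genes, which are not independent replicates, were 0.958 to 0.985 among transgenic vehicle hearts, 0.974 to 0.984 among wild type hearts and 0.909 to 0.941 between these groups. The first principal component held 56.7% of the variance and separated transgenic from wild type hearts.

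The first question was whether the hearts carried the transgene and responded to it. Ppp3ca, the gene of the calcineurin A α subunit (chromosome 3, positions 136670124 to 136937727 in GRCm38), was at 1222 ± 887 FPKM (SD, n = 3) in transgenic vehicle hearts and 1485 ± 72.1 (SD, n = 2) in JIB-04 hearts. In wild type hearts it was at 23.8 ± 0.862 FPKM (SD, n = 4). The spread in the vehicle group came from heart 3, at a log2 level of 7.64 against 10.78 and 10.74 in hearts 1 and 2. Rcan1, a target and feedback inhibitor of calcineurin (chromosome 16, positions 92391953 to 92466146), was at 104 ± 34.0 FPKM (SD, n = 3) in transgenic vehicle and 154 ± 21.1 (SD, n = 2) in JIB-04 hearts, against 27.6 ± 1.8 (SD, n = 4) in wild type. Over all transgenic against all wild type hearts, the mean log2 level was higher by 5.42 for Ppp3ca and by 2.07 for Rcan1, and every transgenic heart lay above every wild type heart. The exact two-sided permutation p was 0.0079 for each gene (n = 5 and 4), also after adjustment over both tests, and is the smallest these group sizes allow. In limma Ppp3ca passed in both comparisons with wild type. In the day 158 hearts alone (2 against 2) it lost its call for transgenic vehicle against wild type, with a log2 fold change of 4.52 (adjusted p = 0.057). Gene-level values do not show whether the transcript of the transgene is counted in full under Ppp3ca.

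**Figure D1:**
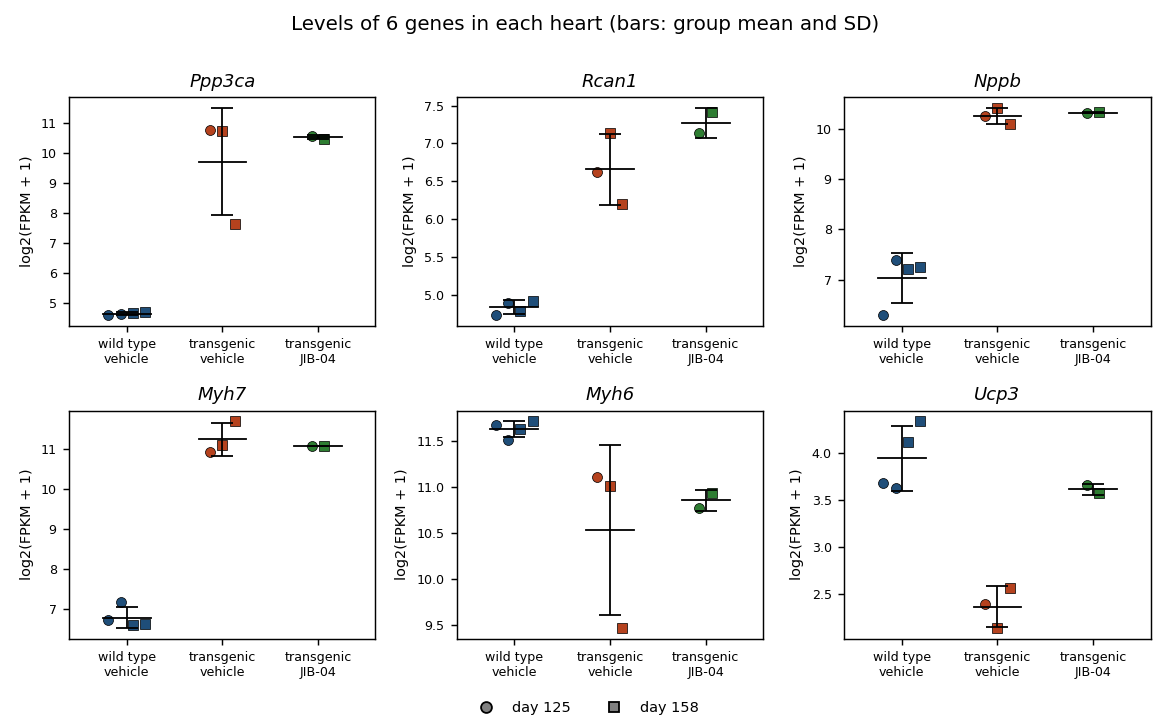
Levels of 6 genes as log2(FPKM + 1) (y axis) in each heart of the wild type vehicle, transgenic vehicle and transgenic JIB-04 groups (x axis), with circles for day 125, squares for day 158 and bars for the group mean and SD. Ppp3ca in transgenic vehicle heart 3 lies at 7.64, between the wild type mean of 4.63 and the other transgenic hearts, and Ucp3 in the JIB-04 hearts (11.2 ± 0.521 FPKM) lies nearer to wild type (14.7 ± 3.76) than to transgenic vehicle (4.20 ± 0.768).

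The second question was what the transgene changed under vehicle. Tpm2, the β-tropomyosin of the thin filament (chromosome 4, positions 43514711 to 43523765), rose from 12.7 ± 1.36 FPKM (SD, n = 4) in wild type to 661 ± 158 (SD, n = 3) in transgenic hearts. Its log2 fold change was 5.58 ± 0.18 (SE), with limma adjusted p = 2.0e-06. Igsf23 rose by 4.89, Ostn, which encodes the secreted peptide osteocrin, by 4.81 and Dkk2, a secreted Wnt antagonist, by 4.75 on the log2 scale. Among the genes that fell most were Ces1d, a carboxylesterase, from 87.0 ± 10.6 to 3.34 ± 1.68 FPKM, Pla2g5, a phospholipase (-3.43 ± 0.23 (SE)), and Lrrc4b (-3.13 ± 0.10 (SE)). Gm15543 (-5.61 ± 0.30 (SE)) and RP24-79E2.2 (-4.98 ± 0.67 (SE)) fell as well. The library kit did not keep strand, and Ostn shares exon positions with Gm32312. In limma 4862 of 13487 genes passed an adjusted p of 0.05, 2739 higher and 2123 lower, and 846 of these changed at least 2-fold (522 higher, 324 lower). The balance of directions depended on scaling. With every heart scaled to the same total, 4489 genes were higher and 1005 lower (81.7% higher against 56.3%), and the median of all genes shifted by 0.20 on the log2 scale. These totals include the mitochondrial genes, some of them listed at 0 in some hearts. Scaling without mitochondrial and the 20 highest genes kept the balance, with 2963 higher and 2002 lower (59.7% higher). Median of ratios turned it, with 2336 higher and 2536 lower (47.9% higher), as did quantile normalization with 2233 and 2540 (46.8%). Fitted within each age, 1124 genes passed at day 125 and 2252 at day 158. Day 125 has 1 transgenic vehicle heart, and the spread in this fit comes from the groups with 2 hearts of a day. A fit of the day 158 hearts alone gave 1217 genes. In simulated data of this size, with 200 changed genes, limma recovered 27.5%, 75.2% and 94.5% of genes changed by 0.5, 1 and 2 on the log2 scale. With so few changed genes the adjusted threshold is stricter than in the real comparison. These shares therefore do not measure how many real changes were missed.

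Genes of the fetal and hypertrophy program rose. These genes are active in the developing heart and again under load. Of 16 tested members 12 were higher and 0 lower (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 9.6e-07; adjusted p = 0.59 with an estimated correlation). Myh7, the β-myosin heavy chain, went from 111 ± 22.3 FPKM (SD, n = 4) to 2482 ± 736 (SD, n = 3), a log2 fold change of 4.46 ± 0.21 (SE). Nppb, the gene of B-type natriuretic peptide (chromosome 4, positions 147985788 to 147987205), rose by 3.18 on the log2 scale. Nppa, of the atrial peptide, went from 299 ± 20.3 to 1889 ± 462 FPKM. The smooth muscle actin gene Acta2 rose by 3.09, but in the day 158 hearts alone (log2 fold change 2.30) it lost its call (adjusted p = 0.12). Myh7 shares exon positions with the non-coding Mhrt, and values without strand cannot separate them.

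Matrix genes rose with them. Of 35 fibrosis and matrix genes 26 were higher and 0 lower (28 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.3e-11; adjusted p = 0.59 with an estimated correlation), with a median log2 fold change of 1.35. Comp, cartilage oligomeric matrix protein, rose from 0.864 ± 0.0492 FPKM (SD, n = 4) to 39.7 ± 12.3 (SD, n = 3). Ctgf, connective tissue growth factor, rose by 3.95 and Tgfb3, a transforming growth factor, by 3.82 on the log2 scale. Of 16 fibroblast markers 10 were higher and 1 lower (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.68 with an estimated correlation), among them Mfap5 (2.09), which is also in the matrix list, and Medag (0.75). The fibroblast list did not pass without transgenic vehicle heart 1 (camera adjusted p = 0.099).

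Genes of oxidative metabolism were lower in 2 lists. Of 39 nuclear genes of oxidative phosphorylation and the citrate cycle 36 were lower and 0 higher (0 higher and 36 lower adjusted over the list alone; camera adjusted p = 1.3e-16; adjusted p = 0.59 with an estimated correlation). Cs, citrate synthase, fell from 463 ± 19.7 FPKM (SD, n = 4) to 238 ± 22.4 (SD, n = 3), and Uqcrc1 of complex III by 0.80 on the log2 scale. Cox7a1, the muscle form of a cytochrome c oxidase subunit, fell by 1.20, but missed the threshold in the day 158 hearts alone (log2 fold change -1.36, adjusted p = 0.054). The median of the list was -0.63 and lay between -0.68 and -0.40 under the other scalings. Of 31 genes of fatty acid oxidation 21 were lower and 1 higher (1 higher and 22 lower adjusted over the list alone; camera adjusted p = 1.9e-07; adjusted p = 0.64 with an estimated correlation). Ucp3, a carrier of the inner mitochondrial membrane, fell by 1.61 and Acaa2, a thiolase of β-oxidation, by 1.48 on the log2 scale. Pdk4, a kinase that restrains pyruvate dehydrogenase, rose by 1.15, but lost its call without transgenic vehicle heart 1 (adjusted p = 0.098) or wild type heart 4 (0.052), in the day 158 hearts alone (log2 fold change 0.72; 0.24) and with no filter on low genes (0.058). Glycolysis genes went both ways, with 6 higher and 9 lower of 20 (6 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.081), for instance the muscle enolase Eno3 (-1.63) and the lactate transporter Slc16a3 (1.17).

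Among genes of calcium handling and ion channels 15 of 36 were lower and 8 higher (8 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.0080; adjusted p = 0.64 with an estimated correlation), but the list did not pass with the replicate number as a block (camera adjusted p = 0.066). Kcnv2, a potassium channel subunit, fell from 4.12 ± 0.84 FPKM (SD, n = 4) to 0.113 ± 0.0428 (SD, n = 3), a log2 fold change of -2.15. Sarcomere genes went both ways, with 9 higher and 5 lower of 25 (10 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.27). Synpo2l, a Z-disc protein, rose by 2.19, and Myom2 of the M-band fell by 2.80, though in the day 158 hearts alone (log2 fold change -2.06) it lost its call (adjusted p = 0.15). Calcineurin and NFAT genes, 4 higher and 4 lower of 15 (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.98), included a fall of the transcription factor Nfatc2 by 0.81 beside the rises of Ppp3ca and Rcan1. Of 24 cytokine and chemokine genes 7 were higher and 3 lower (7 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.74). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 2.59, and Ccl11, an eosinophil chemokine, fell from 1.11 ± 0.127 to 0.057 ± 0.0543 FPKM. Of 28 genes of the Jumonji family, the target class of JIB-04, 2 were higher and 1 lower (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.85). Tyw5 rose by 0.72 and Jarid2 fell by 0.55, and both lost their calls in the day 158 hearts alone (log2 fold changes 0.50 and -0.66, adjusted p = 0.13 and 0.053) and Jarid2 also with equal totals (0.074). Kdm3a, at 0.43 (adjusted p = 0.043), lost its call under most alternatives, up to 0.12 without wild type heart 3. Tyw5 shares exon positions with Maip1.

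Interferon response genes were lower, with 1 higher and 12 lower of 21 (1 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.00011; adjusted p = 0.68 with an estimated correlation), for instance Rsad2 (-1.28) and Irf7 (-0.94). Endothelial markers were lower, with 3 higher and 10 lower of 18 (3 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.68 with an estimated correlation). Tie1, an endothelial receptor kinase, fell by 0.95, while Npr3, the clearance receptor of natriuretic peptides, rose by 3.43 on the log2 scale. Immediate early genes were higher, with 8 higher and 2 lower of 22 (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.027; adjusted p = 0.81 with an estimated correlation), for instance Btg2 (1.38); this list did not pass without transgenic vehicle heart 3 (camera adjusted p = 0.11) or with the replicate number as a block (0.099). Of 13 genes of the mitochondrial chromosome 8 were lower (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0041; adjusted p = 0.59 with an estimated correlation), but the call was lost after quantile normalization (camera adjusted p = 0.72). That list holds mt-Atp6, mt-Atp8 and mt-Co3, listed at 0 in 7 hearts, and its median (-0.46) and mean (0.93) differ in sign. Macrophage markers did not pass as a list (1 higher and 0 lower of 18), although Lgals3, galectin-3, rose by 4.17.

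The other lists did not pass in camera. Among markers of cell types these were lymphocytes (0 of 3 genes called), neutrophils and mast cells (0 higher and 2 lower of 5; median 0.62, though camera pointed down), smooth muscle and pericytes (3 higher and 7 lower of 14), atrial cardiomyocytes (3 higher and 2 lower of 11), the conduction system (1 higher and 2 lower of 4) and adipocytes (1 higher and 0 lower of 4). Epicardial (1 higher and 0 lower of 3), erythroid (0 of 7 called), Schwann and neuronal (1 higher and 0 lower of 4) and skeletal muscle markers (0 higher and 2 lower of 4) did not pass either. Among responses these were the unfolded protein response (7 higher and 1 lower of 22), hypoxia (7 higher and 2 lower of 18), NRF2 and xenobiotic response (8 higher and 3 lower of 18), iron handling (2 higher and 2 lower of 13), cell cycle (1 higher and 1 lower of 16) and apoptosis (9 higher and 2 lower of 17). Clock genes (5 higher and 3 lower of 18), ribosomal protein genes (2 higher and 1 lower of 32) and the 1 sex-linked gene tested, Xist (29.9 ± 5.23 FPKM in wild type and 30.3 ± 4.41 in transgenic vehicle hearts), did not pass. Counts adjusted over the list alone were the same in these lists except for hypoxia (8 higher and 2 lower), iron handling (1 higher and 2 lower), cell cycle (0 higher and 1 lower), apoptosis (10 higher and 2 lower), clock (5 higher and 5 lower), adipocyte (1 higher and 1 lower) and Schwann and neuronal genes (1 higher and 3 lower). In all, 10 of 35 lists passed with the preset correlation, 0 with an estimated one (1 at an unadjusted p under 0.05), and 18 in the rotation test fry, which asks whether the genes of a list move together and not whether they stand apart from other genes.

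**Figure D2:**
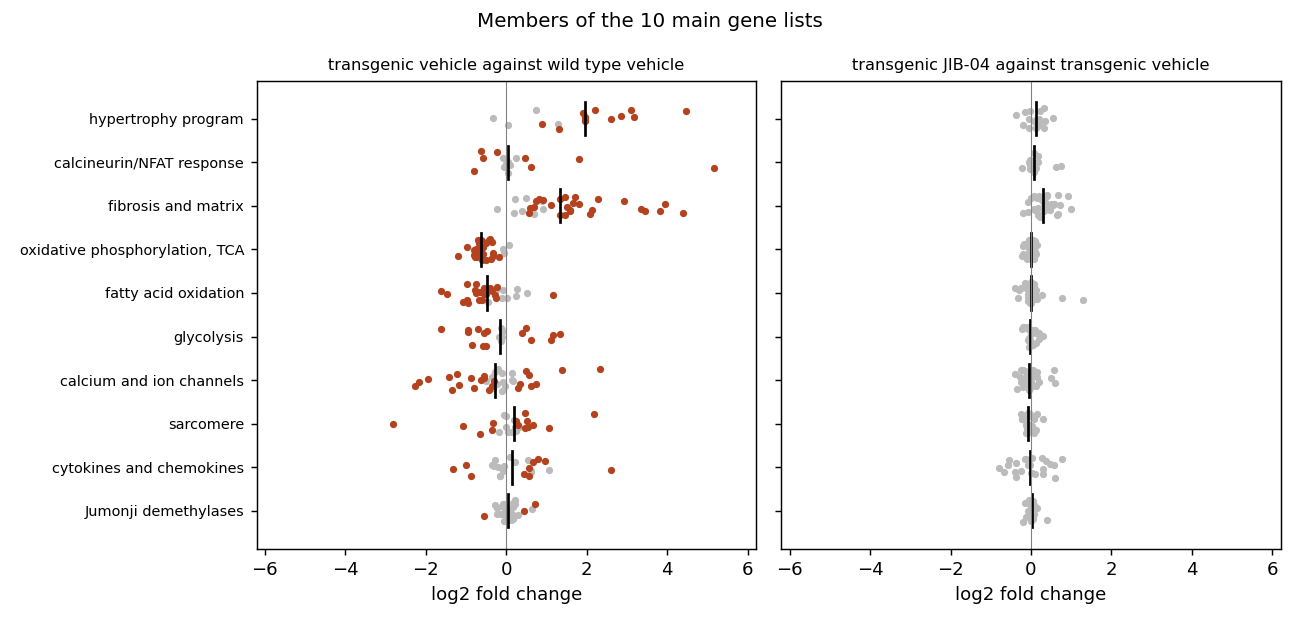
Log2 fold changes (x axis) of the tested members of the 10 main gene lists (y axis) between transgenic and wild type vehicle hearts (left) and between JIB-04 and vehicle transgenic hearts (right), with each gene a point, red where its adjusted p is under 0.05, and black bars at list medians. On the left 36 of 39 genes of oxidative phosphorylation and the citrate cycle are lower, and on the right no member of these lists is red.

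The third question, which the series title names, was what JIB-04 changed in transgenic hearts. The 16 genes of the fetal and hypertrophy program did not pass as a list, with 10 above 0 and a median of 0.11 on the log2 scale (camera adjusted p = 0.34; adjusted p = 0.92 with an estimated correlation). Nppb was at 1277 ± 11.9 FPKM (SD, n = 2) with JIB-04 and 1225 ± 134 (SD, n = 3) with vehicle, and the 95% interval of the log2 difference was -0.55 to 0.75. Myh7 was at 2165 ± 4.25 and 2482 ± 736 FPKM (interval -0.73 to 0.41), and Nppa at 2256 ± 98.4 and 1889 ± 462 (interval -0.05 to 0.69). Each of these had limma adjusted p = 0.99. Ucp3, which fell with the transgene, was at 11.2 ± 0.521 FPKM with JIB-04, 4.20 ± 0.768 with vehicle and 14.7 ± 3.76 in wild type hearts (log2 difference 1.28 ± 0.20 (SE), interval 0.82 to 1.75, adjusted p = 0.42). Aqp1, a water channel of endothelium, differed by -0.69 ± 0.14 (SE) and Ankrd37, a hypoxia-responsive gene, by -1.29 ± 0.35 (SE), each short of the threshold (adjusted p = 0.99 for both). Ankrd37 shares exon positions with Lrp2bp and Ufsp2.

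One of 13487 genes passed in this comparison. It was Gm15776 (chromosome 16, positions 22295027 to 22295231), listed at 0 in the 7 hearts without JIB-04 and at 6.66 and 11.2 FPKM in the JIB-04 hearts (adjusted p = 0.0011). It was not matched to the annotation used here. Its call was lost with a pseudocount of 0.1 (adjusted p = 0.17), with a filter of 5 FPKM (0.18) and in a fit of the transgenic hearts alone (0.12). Without JIB-04 heart 1 or 2 it was not tested, since it then reached 1 FPKM in a single heart. Next in rank was Tcf15, a transcription factor, with a log2 difference of -0.88 and adjusted p = 0.16, chosen after its values were seen. At an unadjusted p under 0.05 there were 444 genes, where chance alone gives 674. The count of 1 became 0 without JIB-04 heart 2, 2 without transgenic vehicle heart 1, transgenic vehicle heart 3 or wild type heart 3, and 3 without transgenic vehicle heart 2. Among protein-coding genes limma called 0, with 390 at an unadjusted p under 0.05. In simulated data of this size 14.9%, 66.9% and 92.4% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered in this comparison, so most changes of 0.5 would have been missed.

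Of 35 lists 5 shifted as a whole in camera with the preset correlation, although none of their members passed alone. Fibrosis and matrix genes were higher with JIB-04, with 31 of 35 members above 0 and a median of 0.29 on the log2 scale (camera adjusted p = 4.5e-08; adjusted p = 0.69 with an estimated correlation). Bgn, the proteoglycan biglycan, was at 312 ± 28.0 FPKM (SD, n = 2) with JIB-04 and 248 ± 54.9 (SD, n = 3) with vehicle. Without JIB-04 heart 2 this list did not pass (median 0.22; camera adjusted p = 0.11). Without transgenic vehicle heart 3 the median fell to 0.09 and the list still passed (camera adjusted p = 0.00015), while it was 0.52 and 0.45 without hearts 1 and 2. Ribosomal protein genes were lower, with 1 of 32 members above 0 (median -0.12; camera adjusted p = 6.3e-06; adjusted p = 0.69 with an estimated correlation), but not without JIB-04 heart 2 (median -0.04; 0.060) or after quantile normalization (median -0.04; 0.052). Genes of the NRF2 and xenobiotic response were lower, with 0 of 18 above 0 (median -0.21; camera adjusted p = 0.00033; adjusted p = 0.69 with an estimated correlation), but not without transgenic vehicle heart 1 (median -0.25; 0.077) or 3 (median -0.13; 0.053). Cbr3, a carbonyl reductase of that list, was at 2.31 ± 0.3 FPKM with JIB-04 and 3.34 ± 0.654 with vehicle.

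Immediate early genes were higher (median 0.24; camera adjusted p = 0.00038; adjusted p = 0.69 with an estimated correlation), with Btg2 at 56.9 ± 17.6 FPKM (SD, n = 2) with JIB-04 and 37.7 ± 3.98 (SD, n = 3) with vehicle. This call was lost without JIB-04 heart 1 (median 0.11; 0.31), the median was 0.43 without JIB-04 heart 2, and without transgenic vehicle heart 1 the median turned to -0.05 (0.71). Cell cycle genes were higher by a median of 0.13 (camera adjusted p = 0.014; adjusted p = 0.69 with an estimated correlation), for instance Mcm5, a replication factor, at 1.58 ± 0.145 and 0.798 ± 0.464 FPKM. This call was lost without transgenic vehicle heart 1 (median 0.19; 0.077) or 3 (median 0.06; 0.34), without JIB-04 heart 2 (median 0.18; 0.16) and with the replicate number as a block (median 0.07; 0.061). The median was 0.27 without transgenic vehicle heart 2. The number of lists was 3 without transgenic vehicle heart 1. The rotation test fry called 0 of 35 lists (smallest adjusted p = 0.60), and at an unadjusted p under 0.05 there were 0 lists in fry and 0 in camera with an estimated correlation. Adjusted over the list alone, Ucp3 was higher among fatty acid oxidation genes and Aqp1 lower among endothelial markers, and neither list passed. The 28 Jumonji genes did not pass (camera adjusted p = 0.81), with 15 above 0, nor did the fibroblast markers (median 0.07; camera adjusted p = 0.25).

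Against wild type hearts, JIB-04 hearts showed changes of the same kind as transgenic vehicle hearts. Tpm2 (5.64 ± 0.21 (SE)), Comp (4.97 ± 0.19 (SE)), Myh7 (4.30 ± 0.23 (SE)) and Nppb (3.28 ± 0.27 (SE)) were higher on the log2 scale. Ces1d (-4.65 ± 0.21 (SE)) and Pde1c, a phosphodiesterase (-3.17 ± 0.11 (SE)), were lower. Ucp3, at -0.33 ± 0.19 (SE), did not pass here (adjusted p = 0.23). In limma 4354 genes passed, 2353 higher and 2001 lower, and 931 of them changed at least 2-fold. With every heart scaled to the same total 2924 were higher and 1074 lower (73.1% higher against 54.0%), with the median of all genes shifted by 0.15. Scaling without mitochondrial and the 20 highest genes gave 2906 higher and 1731 lower (62.7% higher). Median of ratios gave 2100 higher and 2327 lower (47.4% higher), and quantile normalization 1989 and 2234 (47.1%). The majority direction depended on scaling here too. The count was 2186 without JIB-04 heart 1, 1720 without JIB-04 heart 2, and 651 in the day 158 hearts alone, where the JIB-04 group is 1 heart.

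Of 35 lists 12 passed against wild type, 4 higher and 8 lower, with 0 under an estimated correlation (adjusted p = 0.55 or more; 2 at an unadjusted p under 0.05) and 16 in fry. Higher were the fetal and hypertrophy program (12 higher and 0 lower of 16; 13 higher and 0 lower adjusted over the list alone), fibrosis and matrix genes (28 higher and 0 lower of 35; 30 higher and 0 lower adjusted over the list alone), immediate early genes (12 higher and 0 lower of 22; 13 higher and 0 lower adjusted over the list alone) and fibroblast markers (10 higher and 1 lower of 16; 10 higher and 1 lower adjusted over the list alone). Lower were oxidative phosphorylation and the citrate cycle (0 higher and 36 lower of 39; 0 higher and 36 lower adjusted over the list alone), fatty acid oxidation (1 higher and 19 lower of 31; 1 higher and 20 lower adjusted over the list alone), calcium handling and ion channels (5 higher and 13 lower of 36; 8 higher and 16 lower adjusted over the list alone), interferon response (1 higher and 8 lower of 21; 1 higher and 9 lower adjusted over the list alone) and endothelial markers (3 higher and 12 lower of 18; 3 higher and 13 lower adjusted over the list alone). Ribosomal protein genes were lower (2 higher and 8 lower of 32; 2 higher and 9 lower adjusted over the list alone; median -0.19), but their median was near 0 after quantile normalization (-0.0080, camera adjusted p = 0.96) and -0.10 without JIB-04 heart 2 (0.046). Genes of the mitochondrial chromosome (0 higher and 8 lower of 13) and skeletal muscle markers (0 higher and 2 lower of 4) were lower, but lost their calls without JIB-04 heart 1 (0.060 and 0.050) and with the replicate number as a block (0.071 and 0.068). The mitochondrial list also lost its call after quantile normalization (0.63), and skeletal muscle markers with a pseudocount of 0.1 (0.091) and after median of ratios scaling (0.056).

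The comparisons of both transgenic groups with wild type share the wild type hearts. They had 3762 called genes in common, 0 of them in opposite directions. Independent lists of these sizes would share 793 genes. Unchanged groups set against the same wild type hearts, with lists of these sizes picked from noise, shared a median of 1516.5 (37.6 to 3311 in 95% of 100 simulations). The covariance of the fold changes across genes was 0.321 against a simulated median of 0.0150, and the correlation 0.92 against 0.41. With a different pair of wild type hearts for each transgenic group, the correlation was 0.817 to 0.856. A further question was whether JIB-04 moved genes against the direction of the transgene. Of the 4862 genes called for the transgene 51.1% differed in the opposite direction between JIB-04 and vehicle hearts. Both comparisons share the transgenic vehicle hearts, which alone pushes genes apart, and unchanged groups gave a median of 81.8% (20.5% to 100%). The correlation across genes was -0.03 against a simulated median of -0.53, and the covariance -0.0043 against -0.0190. The simulated genes were picked from noise alone, while the real 4862 hold transgene effects that sharing hearts hardly turns. The simulated share and correlation are therefore no baseline for the real ones, and no conclusion is drawn from them. With 3 transgenic vehicle hearts the shared group cannot be split into pairs, so part of any opposite movement may come from sharing. In limma 0 genes were called in both comparisons with opposite sign, where only 1 gene was called between JIB-04 and vehicle hearts.

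**Figure D3:**
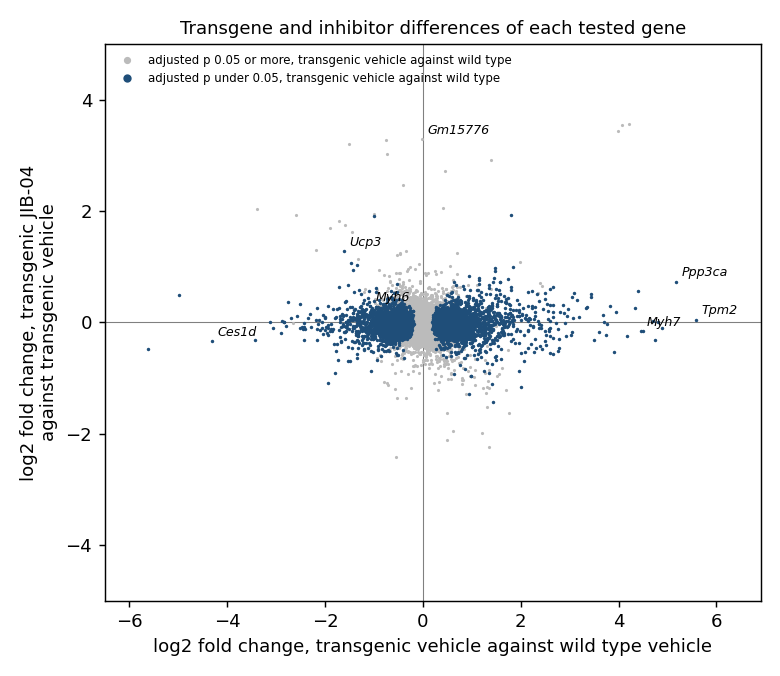
Log2 fold change of each tested gene between transgenic and wild type vehicle hearts (x axis) and between JIB-04 and vehicle transgenic hearts (y axis), with the 4862 genes called for the transgene coloured. The coloured cloud extends along the horizontal axis (correlation -0.03 over all genes), and Gm15776 is the gene called for JIB-04.

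The last comparison was between the days of collection, over all groups. Genes of the mouse placenta showed the strongest difference. Prl3b1, placental lactogen 2 (chromosome 13, positions 27242430 to 27249679), was at 7.82 FPKM in transgenic vehicle heart 1, 17.2 in JIB-04 heart 1, and 8.98 and 12.6 in wild type hearts 1 and 2. It was listed at 0 in all 5 day 158 hearts (limma adjusted p = 0.00032). Tpbpb, a trophoblast gene, was at 4.61 to 8.51 FPKM in the day 125 hearts and listed at 0 at day 158, and Ctsq, a placental cathepsin, was at 4.90 to 10.5 FPKM and at most 0.043. These genes were chosen after their values were seen. Of 30 genes lower at day 158, 13 belong to a list of 70 placental genes of the prolactin, pregnancy-specific glycoprotein, cathepsin, Ceacam, Tpbp and other families, written after the calls were seen. Among 21 genes higher at day 158, and likewise chosen after their values were seen, were Slc8a1, the sodium-calcium exchanger of heart muscle (0.87 ± 0.09 (SE)), and Myocd, the co-activator myocardin (0.56 ± 0.06 (SE)). In limma 51 genes were called, with 2534 at an unadjusted p under 0.05. Of protein-coding genes tested alone 29 were called. The count moved by more than 1.5 times without any single heart. It was 19, 287 and 131 without transgenic vehicle hearts 1, 2 and 3, 17 without either JIB-04 heart, and 11, 16, 23 and 9 without wild type hearts 1, 2, 3 and 4.

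**Figure D4:**
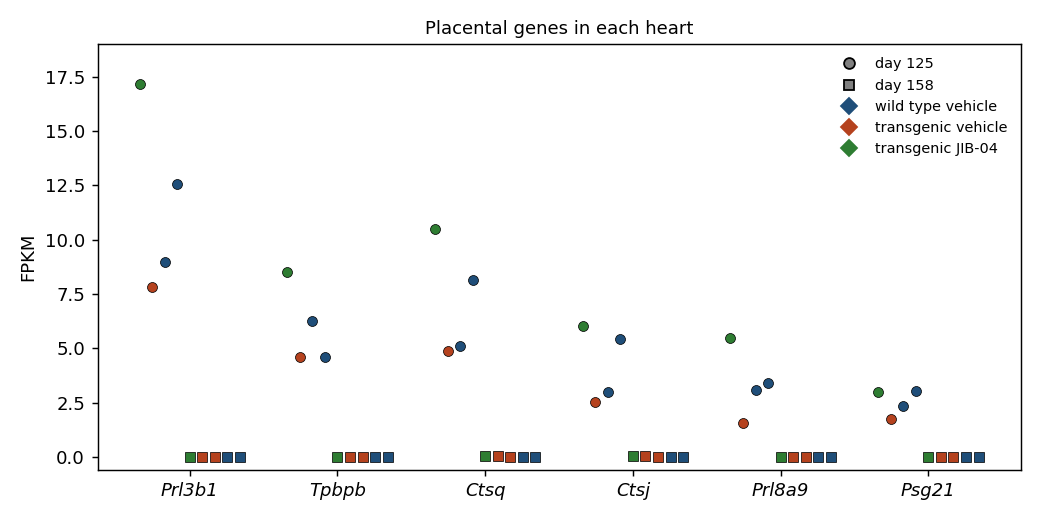
FPKM (y axis) of 6 placental genes (x axis) in each of the 9 hearts, coloured by group, with circles for day 125 and squares for day 158. The 4 day 125 hearts, from all 3 groups, lie above 0 for each gene (Prl3b1 at 7.82 to 17.2), and the day 158 hearts at or near 0.

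The effect of the transgene differed between the days for 1 gene of 13487 in limma, Gm11382, with 401 genes at an unadjusted p under 0.05. Gm11382 was at 51 and 70.1 FPKM in the day 125 transgenic vehicle and JIB-04 hearts and listed at 0 in the other 7 hearts. The count was 0 among protein-coding genes and 186 with no filter on low genes. The effect of JIB-04 differed between the days for 0 genes in limma, with 405 at an unadjusted p under 0.05, and rested on 1 JIB-04 heart per day.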

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

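None of the searches for single hearts or differences between days in this part was chosen after its result was seen. The named genes were searched for a wild type heart that stood apart from the other wild type hearts, by the gap to its nearest neighbour as a share of the range of the group. Of 150 genes checked, 6 had such a heart, where chance sets apart about 1 in 20, or 7.5. Nppb, the gene of B-type natriuretic peptide, had a gap of 0.842, with wild type heart 1 at a log2 level of 6.30 and the nearest other at 7.21. The other 5 set wild type heart 2 apart. Among these were Ostn with a gap of 0.971, from levels near 0 (0.07 against 0.00), the sarcomere gene Actn2 with 0.874 (9.14 against 9.23), the macrophage marker Ms4a7 with 0.890 (1.68 against 1.17) and the interferon response gene Oas2 with 0.843 (3.30 against 2.6). The number does not exceed what chance gives. Whether wild type heart 2 is set apart more often than the other wild type hearts was not tested.

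The effect of the transgene differed between day 125 and day 158 for Gm11382, with a log2 difference of -5.70 (limma adjusted p = 0.0029). It was at 51 and 70.1 FPKM in transgenic vehicle heart 1 and JIB-04 heart 1, and listed at 0 in the other 7 hearts. The difference rests on 1 transgenic vehicle heart at day 125, and no explanation for it was tested.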

How the results depend on the processing

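The alternatives were chosen before the data were examined, except the restriction to protein-coding genes, chosen after seeing the data. Alternatives that work on counts were not run, because the files used here hold no counts. In limma Ppp3ca lost the threshold in the day 158 hearts alone, for transgenic vehicle against wild type (adjusted p = 0.057).

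The number of genes for transgenic vehicle against wild type was 1217 in the day 158 hearts alone, where fewer hearts were compared, and 3348 to 5008 with each heart left out. For JIB-04 against wild type it was 651 in the day 158 hearts alone, with 1 JIB-04 heart, and 1720 to 5322 with each heart left out. For JIB-04 against transgenic vehicle it was 0 with a pseudocount of 0.1, a filter of 5 FPKM, day 158 hearts only or protein-coding genes only, 2 with no intensity trend, 6 with no filter, and 0 to 3 with each heart left out. For day 158 against day 125 it was 23 with no filter, 175 when scaled without mitochondrial and the 20 highest genes, 29 for protein-coding genes, and 9 to 287 with each heart left out. Genes whose transgene effect differed between days numbered 0 with a pseudocount of 0.1, a filter of 5 FPKM or protein-coding genes only, 4 with equal totals and 186 with no filter. Where a heart was left out of the JIB-04 group, or day 158 hearts only were used, the 1 remaining JIB-04 heart is assumed to vary like the other groups. The cause was not tested, other than the smaller number of hearts or genes.

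For transgenic vehicle against wild type, 0 lists passed with an estimated correlation and 18 in fry, and 9 to 13 with each heart left out. For JIB-04 against vehicle it was 0 with either, and 3 to 7 with each heart left out. For JIB-04 against wild type it was 0 with an estimated correlation, 16 in fry and 11 to 13 with each heart left out. Ribosomal protein genes in JIB-04 against wild type turned from down to up in camera after quantile normalization, with a median of -0.0080 (adjusted p = 0.96). The share of genes moving against the transgene under JIB-04 was 47.3% to 60.4% with each heart left out and 46.1% among genes changed at least 2-fold.

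A value of a named gene was kept under an alternative if a called gene stayed called in the same direction. Without a call, it was kept if it stayed uncalled and moved by less than the spread between hearts, whatever its sign. For transgenic vehicle against wild type 1863 values were kept, 93 lost the threshold, 23 gained it and 3 moved by more than the spread. For JIB-04 against vehicle 1495 were kept, 3 lost the threshold and 55 moved. For JIB-04 against wild type 1826 were kept, 105 lost it, 14 gained it and 10 moved. No named gene with a call in either fit reversed. Direction was not compared for genes without a call. For JIB-04 against vehicle only 1 gene was called in the main fit, so direction was hardly tested there.

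With the replicate number as a block in place of day (replicate block), 4079 genes passed for transgenic vehicle against wild type, 1 for JIB-04 against vehicle and 3416 for JIB-04 against wild type. The numbers do not pair the hearts. Deviations of 7 same-number pairs correlated at -0.19 to 0.43, and 3 of 9 hearts correlated best with a heart of their own number, while the median was 0.18 for hearts of the same day and -0.18 for hearts of different days.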

Other observations

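The tests of the myosin promoter, of fibroblast share, of genes that vary together and of failed estimates were chosen only after the result was seen, and the list of placental genes was written after the genes that differ between days were seen. Ppp3ca was lower by 3.12 on the log2 scale in transgenic vehicle heart 3 than in the other transgenic vehicle hearts. Nppb and Myh7 in this heart were near or above the level of those hearts. Acta2 (log2 level 6.71 against 9.06 and 8.93) and Casq1 (2.68 against 5.34 and 5.48) were lower in it, as Ppp3ca was. Dilution with wild type heart RNA would bring all genes changed by the transgene near the wild type level, but 864 such genes lay at a median position of 0.916 (0 is the wild type mean, 1 the mean of the other transgenic vehicle hearts), with Ppp3ca at 0.102, Rcan1 at 0.495, Nppb at 0.834 and Myh7 at 1.65. A difference of depth or scaling is argued against by a median log2 difference of all genes of -0.029. Equal loss of output of the myosin promoter is argued against by Myh6, which was lower in this heart by less than Ppp3ca (-1.60 against -3.12, a difference of -1.515). A lower output of the transgene in this heart, or a difference in which part of its transcript was counted, stays open, and no biological explanation was tested.

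Fibrosis and matrix genes were higher in JIB-04 than in vehicle hearts by a median of 0.29 on the log2 scale. Without transgenic vehicle heart 3 the median was 0.0895, under the size of 0.1 set in advance for an effect of that heart alone, which is consistent with most of the shift resting on this heart. A demand that the camera call also be lost was added after the result was seen and is not used here. The call was kept (adjusted p = 0.00015), so whether this heart accounts for the whole shift stays open. To test a larger share of fibroblasts, 15 fibroblast markers outside the list were taken, with a median of 0.06, below that of the list by -0.23. The spread of this difference was taken over genes and not over hearts. The mean level of the fibroblast list, relative to wild type, was also lowest in transgenic vehicle heart 3. It was 0.20 there, 0.64 and 0.72 in hearts 1 and 2, and 0.74 and 0.61 in the JIB-04 hearts. A difference in fibroblast share therefore stays open. Spread between hearts in genes that vary together is consistent with the shift, since fry gave an adjusted p = 0.60. An effect of JIB-04 on matrix genes stays open beside it.

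The placental genes of the day 125 hearts may come from RNA or reads of placenta in those libraries. Beside the genes called between days, 47 markers were above 0. Of these, 24 were higher in every day 125 heart than in every day 158 heart (51.1%, where chance gives 0.794%). The exact binomial 95% interval, 36.1% to 65.9%, takes the markers as independent. They were measured in the same hearts, and many share gene families with the called markers, so they may move together. Neither the interval nor the chance share therefore measures how uncertain this share is. The 70 markers summed to 40.0 to 86.9 FPKM in the day 125 hearts and 1.49 to 3.62 in the day 158 hearts, led by Prl3b1 (7.82 to 17.2), Ctsq and Tpbpb, and 2 of them reached 1 FPKM in any day 158 heart. Failed estimates of single genes at day 158 are argued against only if such failures strike genes of any kind. Many of the markers lie close together on chromosomes 7 and 13. Failures confined to a locus or gene family would escape this test and stay open. Of 11226 other genes not called between days, in the same range of highest FPKM, 122 were higher in every day 125 heart, 1.09%. This is below the share among these markers by 50.0 points, a difference with no reliable interval, since these markers may move together. The day of collection and a batch of handling or sequencing fall together here and cannot be told apart, and an effect of the age of the mice was not tested.

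Other splits of the hearts were counted. For transgenic vehicle against wild type, 1 of 35 splits of the 7 vehicle hearts, the real one, gave 4862 genes or more. This is the smallest share these hearts allow, and it argues against chance for the count of genes. The highest other gave 3, but every other split mixes transgenic and wild type hearts, which widens the spread and lowers the count. For the count of lists chance is not argued against, since 6 of 35 splits gave 10 lists or more and the highest other gave 13. For day 158 against day 125, 3 of 100 splits of the 9 hearts, the real one among them, gave 51 genes or more. This is under the limit set in advance. The splits were the real one and a random draw of the others, from 125 whose term can be estimated. Many divide the groups less evenly than the real split, which makes their difference less precise and lowers the count. No conclusion on chance is therefore drawn from this share. The highest other gave 275. That split set transgenic vehicle hearts 1 and 2 and both JIB-04 hearts against transgenic vehicle heart 3 and the wild type hearts, and with a mean fitted for each group it varies only within the transgenic vehicle hearts. Its count points to heart 3 standing apart from hearts 1 and 2, with 1 heart on one side, and no wider structure was tested.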
